A study of Rattus norvegicus with 4 samples.

How the data were processed

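The 4 samples are two-colour oligonucleotide arrays on glass slides. Each array compared total RNA of the right atrium of 1 obese male SHHF rat with that of 1 lean male SHHF rat, all aged 10 months, per the labels. SHHF (spontaneously hypertensive, heart failure) rats carry the corpulent allele of the leptin receptor gene, and homozygous carriers become obese. Lean rats can carry 0 or 1 copy of that allele, and dilated cardiomyopathy starts earlier in obese rats, per the labels. RNA was reverse transcribed with dCTP coupled to Cy3 or Cy5, per the labels' protocols. The obese RNA was in Cy5 on 2 arrays (obese rat 5 against lean rat 3, and obese rat 4 against lean rat 4) and in Cy3 on 2 arrays (obese rat 3 against lean rat 4, and obese rat 1 against lean rat 5). Lean rat 4 was therefore on 2 arrays, and the titles name 3 lean rats where the design text counts 4. The extraction protocol names the left ventricle as the tissue, whereas every other label names the right atrium.

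The deposited table holds 1 log10 ratio per probe and array, as the values themselves show. Within each array, many repeated values lay log10 of small whole-number ratios apart. With the commonest value of an array taken as a ratio of 1, 46.8% to 58.7% of the values shared by at least 5 probes were ratios of whole numbers up to 30 (relative tolerance 1e-05), against 0.409% to 0.455% of values held by 1 probe. Such repeats are expected of very dim spots, whose intensities are small whole numbers. The deposited columns each had a mean of 0, so the authors had centred every array on its mean. The whole-number spacing of the matching values leaves no sign of an intensity-dependent correction of those spots. Whether other spots received one was not tested. The scanner, image software, background correction and normalization are not given in the sources used here, and neither is the numerator of the ratio. No intensities were used here, so signal over background is unknown apart from the repeated values, and the number of arrays limits the precision.

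Values were multiplied by log2 of 10 to give log2 ratios, and the authors' centring was kept. The design had assumed log2 values. Of 28800 probes, 28702 had a value on all 4 arrays and were tested. Only 160 probes, 16 wells for each of 10 control genes, were paired with a gene by the platform annotation used here (1 gene symbol per probe, none with several). The other 28640 are unnamed here. For 2 genes the array symbol was updated through the synonyms of the GRCr8 gene table, from Gapd to Gapdh and from Tcfe2a to Tcf3. Probe names have the form of a plate number, a well row and a well column, and were read as 75 plates of 16 rows and 24 columns.

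Because the numerator is not stated, 2 contrasts were fitted. In the alternating contrast, the sign of the 2 arrays with obese RNA in Cy3 was turned before averaging; it measures obese against lean if the columns hold Cy5 over Cy3, and the dye if they hold obese over lean. In the common contrast, all 4 columns were averaged as deposited, and the reverse holds. The rule fixed before the data were examined compared the covariance of the 2 arrays that share lean rat 4 with the other 3 pairs of opposite dye orientation; it fell between them, and the default of Cy5 over Cy3 was kept for the main test. The overall sign of both contrasts (obese over lean or its inverse) rests on the same default.

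The main test was limma 3.58.1 (lmFit and eBayes, R 4.3.3) of the mean of 4 turned log2 ratios against 0, with Benjamini-Hochberg adjustment over all probes and a threshold of 0.05. The array is the replicate, so p-values measure the spread between 4 pairs of rats, of which 2 share a lean rat. Control genes were tested as the mean over their wells, in a fit with gene means in place of probes. Exact sign-flip tests on 4 arrays cannot give a two-sided p below 0.125. On 4 simulated arrays of 28702 probes, with variances drawn from the prior that limma estimated for the alternating contrast, the test recovered 0 of 50 probes changed by 0.5 on the log2 scale, 40 of 50 changed by 1, 48 of 50 changed by 2 and 50 of 50 changed by 4, with 12 false calls. The simulated arrays were independent, whereas 2 of the 4 arrays here share lean rat 4. Recovery and false calls on these data can therefore differ. When an offset of 0.5 was simulated in well columns 10 to 12 and 22 to 24, 5580 false calls arose. After well-position medians were subtracted, 11 false calls remained. That offset was the same on every array and constant within each position group. Its removal was therefore built in and does not show how well the subtraction works on these data.

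The alternatives fixed in advance were the other reading of the columns, a dye term, median centring, scaling, quantile normalization, leaving out each array, counting lean rat 4 once, filters, robust and weighted fits and a fold threshold. Further choices were made after seeing the data. Values shared by at least 5 probes of an array were called repeated. Leaving out probes that hold one was a planned filter for the count of probes, with 18100 probes left, and was added for the control genes and the correlations. Well-position groups are the 48 combinations of row modulo 4 and column modulo 12, whose medians were subtracted per array, in some alternatives with plate medians as well. The medians came from all probes unless stated, and were also taken over probes without repeated values alone. Leaving out plates 74 and 75, fitting each dye orientation alone, counting lean rat 4 once without repeated values and taking medians over the wells of a gene were also added. The rule for named genes took up to 12 genes per direction from the named probes with 1 sign on all arrays, those past the threshold first, up to 4 members of each gene list and a fixed set of genes. All 10 named genes are given here, and the fixed genes (among them Lepr, Nppa and Pdk4) have no named probe here. Gene lists needed 5 measured members for a test with camera, and no list had them.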

Results

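Transcript levels in the right atrium of obese and lean SHHF rats were compared on 4 two-colour arrays, to ask how obesity changes the atrial transcriptome in this hypertensive, heart-failure-prone strain. Each array held 1 obese and 1 lean rat of 10 months. The 4 obese rats were numbered 5, 3, 4 and 1, and their lean partners 3, 4, 4 and 5. Of 28800 probes, 28790, 28782, 28798 and 28730 had a value on these arrays in that order. The standard deviation of the log2 ratios was 0.58, 0.48, 0.50 and 0.42. Values shared by at least 5 probes of an array, which are ratios typical of very dim spots, made up 16.1%, 13.4%, 13.8% and 16.7% of the values. Only 10 control genes, at 16 wells each, could be named.

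Among the named genes, Lxn, which encodes latexin, an inhibitor of carboxypeptidases, was the 1 gene past the threshold in the planned test over all 16 wells. Its mean log2 ratio in the alternating contrast was -0.65 (SE 0.10, n = 4 arrays, limma adjusted p = 0.0490), negative on 4 of 4 arrays after turning. Negative values in this contrast mean lower in obese atrium if the columns hold Cy5 over Cy3, and measure the dye if they hold obese over lean. The ribosomal protein gene Rps9 was at 0.30 (SE 0.11, adjusted p = 0.149), the ribosomal protein gene Rpl5 at 0.16 (SE 0.10, adjusted p = 0.330) and the topoisomerase gene Top1 at 0.03 (SE 0.10, adjusted p = 0.876). The glycolytic genes Gapdh, encoding glyceraldehyde-3-phosphate dehydrogenase, and Ldha, encoding lactate dehydrogenase A, were at -0.29 (SE 0.11, adjusted p = 0.157) and -0.22 (SE 0.11, adjusted p = 0.253). With the 2 arrays that share lean rat 4 averaged into 1 replicate, Lxn was at -0.59 and did not pass (adjusted p = 0.128). With 3 arrays its ratio stayed near the size of the main test. It passed without obese rat 1, at -0.71 (adjusted p = 0.0350), but not without obese rat 5 (-0.69, adjusted p = 0.155), obese rat 3 (-0.56, 0.139) or obese rat 4 (-0.63, 0.183), and its common contrast was 0.04 (SE 0.30). In the common contrast none of the 10 genes passed the test, nor had any an unadjusted p under 0.05. Its means lay between -0.20 (SE 0.15, Gapdh) and 0.15 (SE 0.10, Top1), with limma adjusted p = 1.00 for each.

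The spread between the wells of a gene was in part tied to repeated values. For Actb, encoding beta-actin, the SD over 16 wells reached 1.76 on the array of obese rat 4, against 0.09 over the 9 wells without repeated values. For Ldha on the array of obese rat 5 it was 0.55 over 16 wells and 0.66 over the 11 without repeated values. Over the 11 wells of Lxn without such a value the mean was -0.19 (SE 0.11, limma adjusted p = 0.277). Tcf3, a transcription factor gene, held such values in 15 of its 16 wells, and its sign rested on them, with -0.36 (SE 0.11, adjusted p = 0.106) over all wells and 0.13 (SE 0.10, adjusted p = 0.400) in the 1 well without. Leaving out these wells, a choice made for genes after seeing the data, put Rps9 at 0.48 (SE 0.12, 13 wells, adjusted p = 0.0332), Top1 at 0.48 (SE 0.11, 11 wells, adjusted p = 0.0285) and Rpl5 at 0.34 (SE 0.10, 15 wells, adjusted p = 0.0573). All 3 were positive on each of the 4 arrays after turning, but with lean rat 4 counted once Rps9 and Top1 did not pass (adjusted p = 0.0800 and 0.0660). Ldha was then at -0.24 (SE 0.11, adjusted p = 0.169) and Gapdh at -0.18 (SE 0.10, adjusted p = 0.276). Whether these oligonucleotides also bind near-identical gene copies was not examined, since probe sequences were not used here.

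Rps9 and Top1 lay in well columns 11 and 12 and 23 and 24, where probes of all kinds had shifted ratios. With the median of each well-position group subtracted and repeated values left out, Rps9 was at 0.18 (SE 0.08, limma adjusted p = 0.221) and Top1 at 0.18 (SE 0.08, adjusted p = 0.227). Rpl5 came from columns 9 and 10, of which column 10 also had shifted ratios. It was at 0.27 (SE 0.09, limma adjusted p = 0.138). Its values per array were 0.03 with obese rat 5 (-0.022 if the medians came from probes without repeated values), 0.37 with obese rat 3, 0.48 with obese rat 4 and 0.17 with obese rat 1. The 2 largest come from the arrays that share lean rat 4, and with that rat counted once the mean was 0.21 (SE 0.10, adjusted p = 0.276). Each of these 3 genes was positive on 4 of 4 arrays, for which the exact sign-flip test gives p = 0.125, the smallest it can give. None of the 10 genes passed the threshold after this subtraction, and the lowest unadjusted p was 0.0187 for Rpl5 (limma). The remaining 7 lay between -0.18 (SE 0.08, Ldha) and 0.05 (SE 0.06, Hspa1a, the inducible heat-shock protein 70). Actb was at -0.00033 (SE 0.08), and Rpn2, which encodes a subunit of the oligosaccharyltransferase, was at -0.0029 (SE 0.07).

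**Figure D1:**
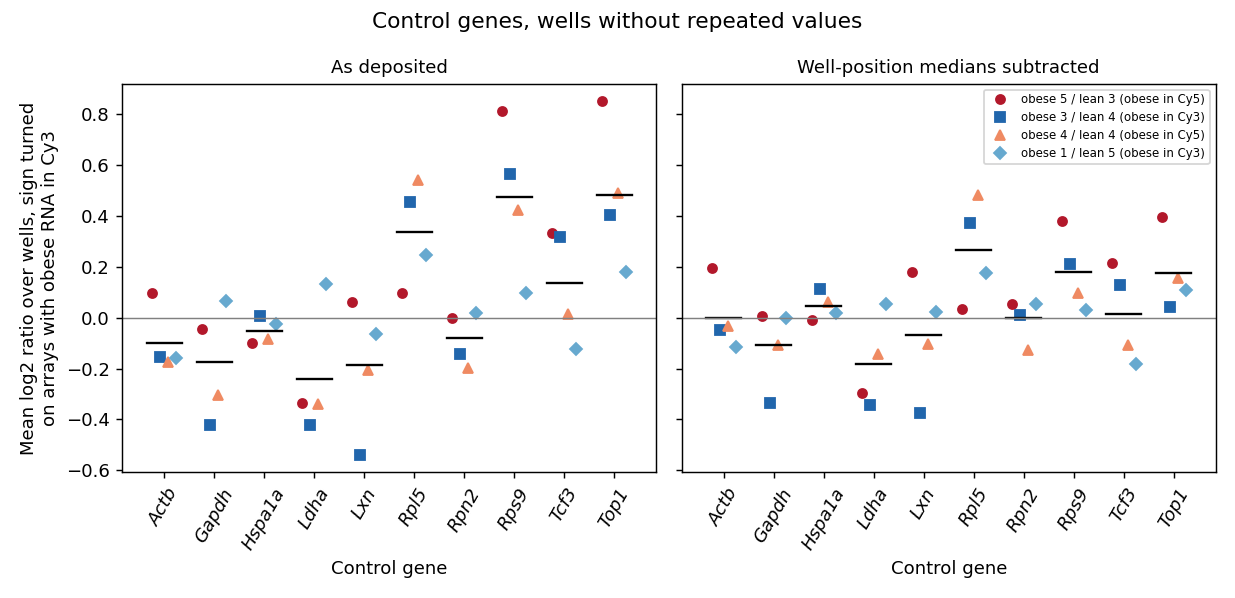
Mean log2 ratio of each control gene over its wells without repeated values, per array (points) and over the 4 arrays (black lines), as deposited (left) and after subtraction of well-position medians (right). The sign was turned on the 2 arrays with obese RNA in Cy3, so positive means higher in obese only if the columns hold Cy5 over Cy3; Rpl5 lies above 0 on all 4 arrays in both panels, and the means of Rps9 and Top1 move from 0.48 to 0.18.

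Of 30 gene lists fixed in advance for atrial metabolism, contraction, matrix, inflammation and cell types, 3 had any measured member. The list of cytosolic ribosomal proteins had 2 of 67 members (Rpl5 and Rps9), that of glycolysis and glucose use 2 of 25 (Gapdh and Ldha) and that of heat shock and the unfolded protein response 1 of 31 (Hspa1a, log2 ratio -0.06, SE 0.07, limma adjusted p = 0.617). Over all wells, 0 members of each passed the limma threshold over all probes and 0 adjusted over the list alone, while Rps9 and Gapdh had an unadjusted p under 0.05 (0.0334 and 0.0378). The lowest adjusted p over the list alone was 0.0668 for Rps9. No list reached the 5 members set for a test of the list, and markers of adipocytes, blood cells, leukocytes, fibroblasts and ventricular myocytes were not measured under a name.

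Across all probes, the alternating contrast called 578 of 28702 (limma, Benjamini-Hochberg adjusted p below 0.05), 379 positive and 199 negative, each with 1 sign on all 4 arrays after turning. Their median size was 0.70 on the log2 scale, or 1.62-fold, with a median SE of 0.10. After subtraction of well-position medians the median size of the same probes was 0.43 (median SE 0.08). The common contrast called 0 probes with limma, and 273 had an unadjusted p under 0.05. Of the called probes, 63.3% lay in well columns 10 to 12 and 22 to 24, which held 24.8% of the tested probes. Plates 74 and 75 held 9.69% of them against 2.65% of the tested probes, and 35.5% had a repeated value on some array against 36.9%. Of the 2 largest positive and 2 largest negative called probes, 3 held repeated values on 1 to 3 arrays, so their sizes are not given. The other was 22K23, with a mean of 1.56 (SE 0.25, adjusted p = 0.0497) and no repeated value. After subtraction of well-position medians without repeated values it was at 1.32 (SE 0.19, adjusted p = 0.0337). Its gene is not named here, and it was chosen after its values were seen.

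The count of called probes was not stable. The 2 arrays that share lean rat 4 were counted as independent, and 18 probes were called with their mean as 1 replicate and 7 with a correlation of 0.5 between them. The count was 12 after subtraction of well-position medians (1 positive, 11 negative), 9 after median centring (1 positive, 8 negative), 2326 without repeated values, 294 with both the position medians and the repeated values removed (50 with lean rat 4 counted once), 55 if those medians came from probes without repeated values (20 with lean rat 4 counted once), and 3, 6, 13 and 1987 without the arrays of obese rats 4, 5, 3 and 1.

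**Figure D2:**
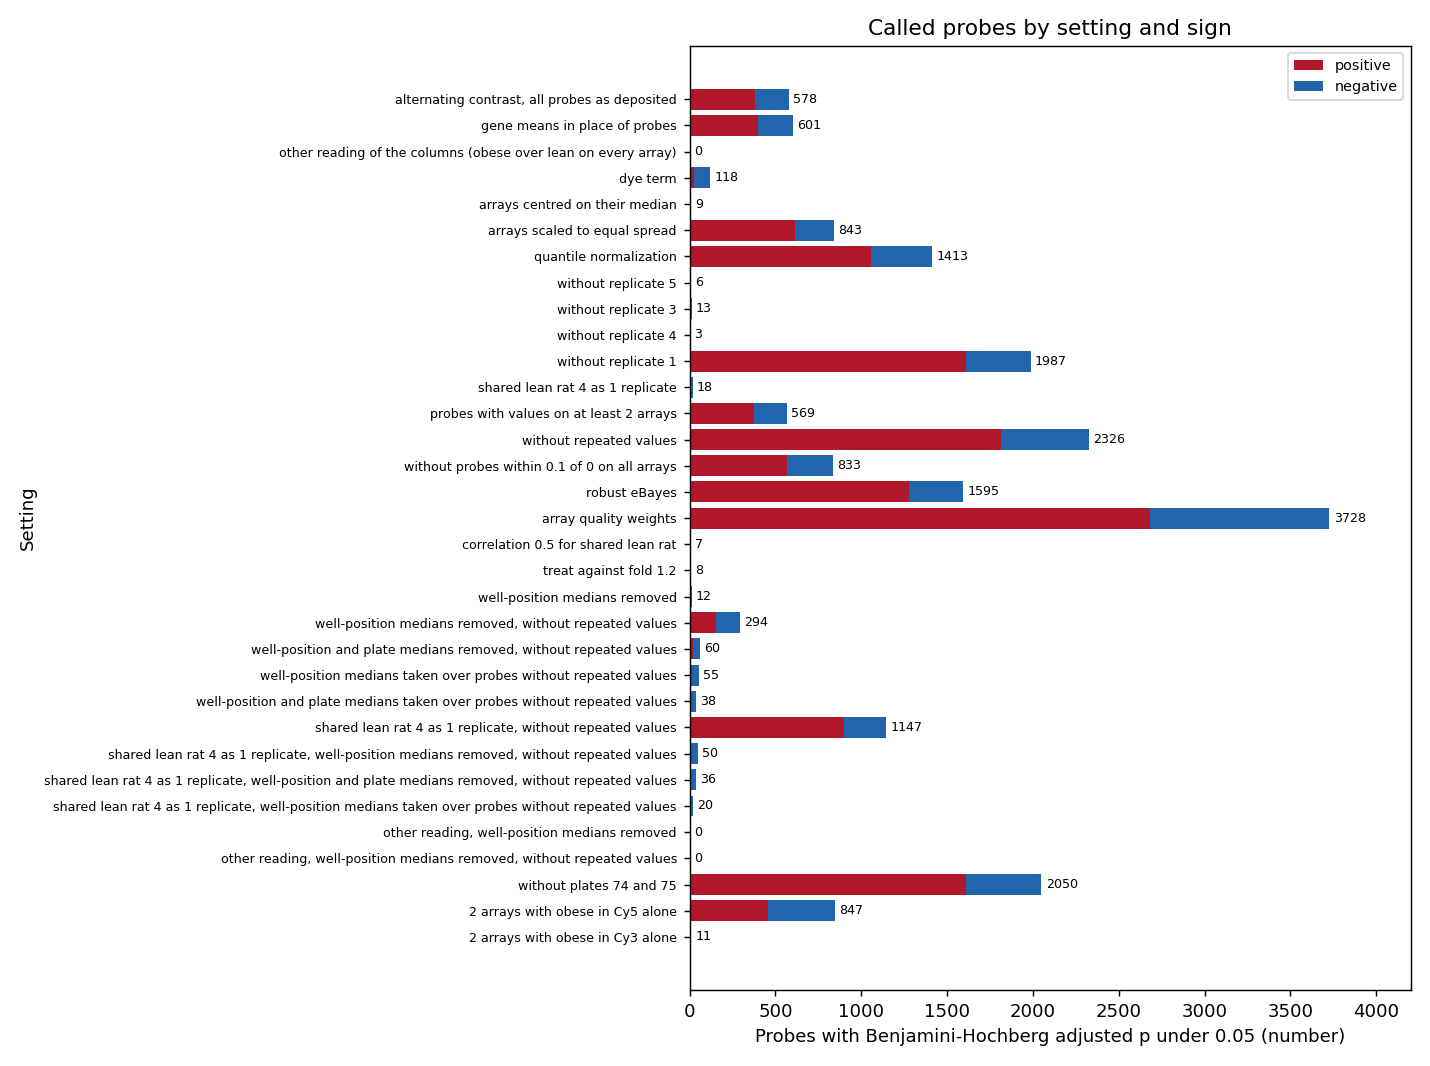
Number of probes with an adjusted p below 0.05 (horizontal axis) under each setting (vertical axis), split by the sign of the mean, in the alternating contrast unless the other reading is named; replicates carry the number of the obese rat, and signs of the 2-array fits at the bottom are as deposited. The count ranged from 0 under the other reading to 3728 with array quality weights, around 578 with all probes as deposited.

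The ratios were then compared between arrays. After turning, all 6 pairs of arrays correlated positively across probes, with Pearson's r of 0.26 to 0.56 and a mean of 0.40 (SD 0.11 over pairs). Probes are not independent replicates. As deposited, the 2 pairs of like dye orientation had r = 0.56 and 0.26, and the 4 pairs of opposite orientation had r from -0.48 to -0.30. With well-position medians subtracted and repeated values left out, r after turning was 0.20 to 0.56. The arrays of obese rats 3 and 4, which share lean rat 4, had a covariance of -0.114 as deposited, between the other 3 pairs of opposite orientation (-0.119 to -0.0628). After both corrections it was -0.0382, below the other 3 (-0.0352 to -0.0197).

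Well position was a measured source of variation. The medians of well columns 1 to 12 recurred in columns 13 to 24, with r from 0.99 to 1.00 across the 12 column pairs of an array. In columns 10 to 12 and 22 to 24 the median log2 ratio was 0.36 and 0.33 on the arrays with obese RNA in Cy5 (obese rats 5 and 4). It was -0.32 and -0.10 on those with obese RNA in Cy3 (obese rats 3 and 1). The 48 well-position groups accounted for 14.5%, 20.8%, 17.9% and 3.49% of the variance between probes on the arrays of obese rats 5, 3, 4 and 1. Without repeated values these shares were 31.6%, 38.2%, 43.9% and 11.4%.

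**Figure D3:**
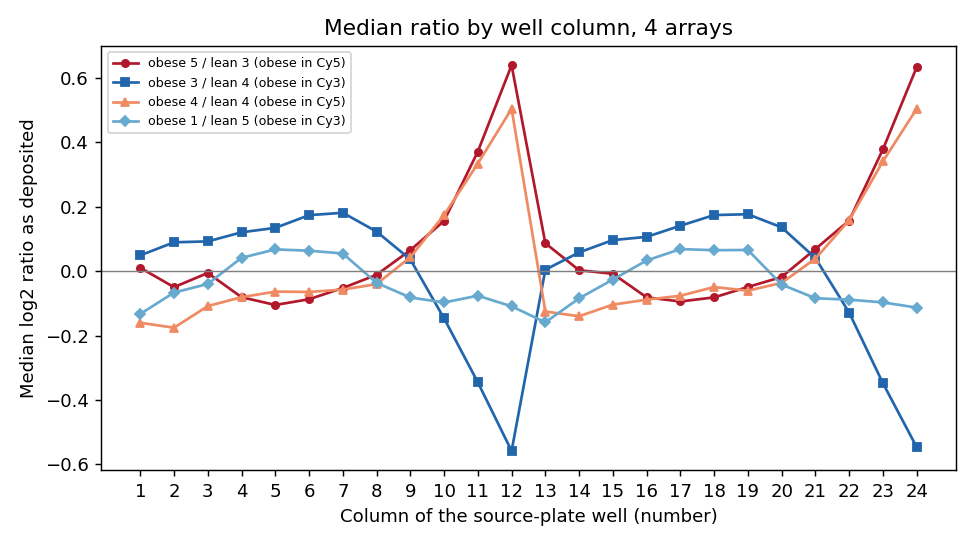
Median log2 ratio as deposited (vertical axis) of all probes from each of the 24 well columns (horizontal axis), 1 line per array. The pattern repeats after column 12. Columns 10 to 12 and 22 to 24 are shifted upward with obese RNA in Cy5 and downward with obese RNA in Cy3. The shift is least on the array of obese rat 1, where columns 1 and 13 lie lower still (-0.13 and -0.16).

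A fit with both an obesity and a dye coefficient was used to look for dye effects per probe. Under the reading Cy5 over Cy3, 0 of 28702 probes had a dye effect past the threshold (limma) and 1075 had an unadjusted p under 0.05, while the obesity coefficient called 118 probes. Under the other reading these 2 counts change places. Without the array of obese rat 4, 5 probes passed for the dye. Within 1 dye orientation, both readings give the same ratio apart from its sign, and obesity and dye cannot be separated. There the mean of the 2 arrays with obese RNA in Cy5 differed from 0 for 847 probes, and that of the 2 with obese RNA in Cy3 for 11. The calls shared 5 probes, each with opposite signs as deposited. At an unadjusted p under 0.05 (limma), the Cy5 arrays had 6555 probes and the Cy3 arrays 2630. They shared 1712, against 601 expected if the lists were independent, and 1647 of the shared probes had opposite signs. Lean rat 4 is on 1 array of each orientation, so these lists are not independent even where nothing changed.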

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

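The tests of explanations in this part were chosen after the results were seen. Leaving out repeated values was planned for the count of probes, but the limit of 5 probes for a repeated value was set after seeing the data. Of 26 measures looked at over the 4 arrays, 1 had an array far from the others, where chance gives about 1.3. It was the median log2 ratio of well columns 10 to 12 and 22 to 24 after turning, which was 0.36, 0.32 and 0.33 on the arrays of obese rats 5, 3 and 4 and 0.10 on that of obese rat 1. The gap to its nearest neighbour was 0.863 of the range.

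The 578 probes called in the alternating contrast may combine technical offsets with other effects. Dim spots with repeated values are not the whole cause. Without them 2326 probes were called, 373 of them among the 578, and 1147 with lean rat 4 counted once. Dim spots whose values were not repeated could not be identified, since no intensities were used, so dim spots in general stay open. Whether offsets shared by each well-position group are the whole cause of those 2326 stays open. With medians taken over all probes, 253 of them kept their call. With medians taken over probes without repeated values, 51 did (37 with plate medians as well). The median size of the 2326 then moved from 0.50 (median SE 0.10) to 0.23 (median SE 0.08), so most calls ended as the differences shrank. Position trends within a group, dye bias per probe and obesity stay open too, as does the shared lean rat, with which counted once 20 of the 2326 were called after this subtraction, 19 of them among the 51. Of the 8 sign patterns of the arrays, only 1 called as many as 578 (highest other 0), and 8 patterns are too few for a share under 0.05.

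The control genes Rps9 and Top1 lay in the shifted well columns. Their means moved from 0.48 (SE 0.12) to 0.179 (SE 0.08) and from 0.48 (SE 0.11) to 0.176 (SE 0.08) when well-position medians were subtracted. The 95% intervals of the lower values, -0.0052 to 0.363 and -0.0086 to 0.361, included 0 and stayed below 0.48. The subtraction lowers ratios in these columns generally, so the fall itself cannot separate position from other effects. Whether position is the whole cause stays open for both genes. The same subtraction left Rpl5 at 0.266 (SE 0.09, 95% interval 0.0584 to 0.473) of 0.34 with the 4 arrays taken as independent, which excludes 0, but at 0.21 (SE 0.10, -0.0213 to 0.446) of 0.28 with lean rat 4 counted once, which does not, so such offsets stay open as its whole cause. Over all wells the same subtraction gave 0.0044 for Rps9, -0.27 for Top1 and 0.09 for Rpl5. Rpl5 did not pass the threshold in any of these fits, and obesity, dye bias, the shared lean rat and chance stay open for it.

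Which contrast measures obesity is not settled by these files. The offset of the commonest value changed sign with the dye orientation on 4 of 4 arrays, at -0.557 and -0.501 (log10) with obese RNA in Cy5 and 0.319 and 0.301 with obese RNA in Cy3. So did the median log2 ratio of plates 74 and 75 (-1.51 and -1.29 against 0.81 and 0.74), the step along the plate numbers (0.16 and 0.07 against -0.08 and -0.18) and the medians of 14 of 24 well columns, 6 of them up and 8 down with obese RNA in Cy5, but not those of the other 10. After turning, the medians of the 48 well-position groups correlated positively in all 6 pairs of arrays, with Pearson's r of 0.46 to 0.95. A scanner or slide follows the dye and not the rat. If these offsets are technical, they argue against columns of Cy5 over Cy3 and point to obese over lean or its inverse. In that case the 578 calls would be dye effects and obesity would have 0. Chance gives such an alternation of 1 measure in 12.5% of cases. The covariance of the arrays that share lean rat 4 points the other way, with a difference of -0.0128 from the mean of the other opposite pairs after both corrections, as columns of Cy5 over Cy3 would give, but at -1.50 of their SD, from 1 pair against 3, it decides nothing.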

How the results depend on the processing

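The alternatives on well position, plates and single dye orientations, and those on repeated values for genes, correlations and a lean rat counted once, were chosen after seeing the data. Against 578 called probes, the count stayed within 1.5 times with gene means (601), equal spread (843), values on at least 2 arrays (569), no probes within 0.1 of 0 (833) and the Cy5 arrays alone (847). Of the calls in these settings, 574, 509, 564, 578 and 198 in that order were among the 578, so the Cy5 arrays alone called mostly other probes. The count was 0 under the other reading (also with position medians removed, with and without repeated values). It was 118 with a dye term, 9 with median centring and 18 with lean rat 4 counted once. It was 7 with a correlation of 0.5 for that rat and 8 against a fold of 1.2. It was 12 with position medians removed, 294 without repeated values as well, 60 with plate medians too, 55 with position medians taken over probes without repeated values, 38 with plate medians so taken too, and 11 on the Cy3 arrays alone. It was 1413 with quantile normalization, 2326 without repeated values, 1595 with robust eBayes, 3728 with array weights and 2050 without plates 74 and 75. With lean rat 4 counted once, it was 1147 without repeated values, 50 with position medians removed as well, 36 with plate medians too and 20 with position medians taken over probes without repeated values. Leaving out 1 array gave 3 to 1987 (1987 without obese rat 1, 3 without obese rat 4), and such fits no longer balance the dyes. The share of positive calls was 65.6% with values as deposited and 11.1% with median centring. Apart from fewer arrays or probes, the cause was not tested. The dye effect stayed at 0 except for 5 probes without obese rat 4 (range 0 to 5). The mean correlation of 0.40 and the covariance difference of the shared pair, -0.0244, kept their sign. Across 19 alternatives each, 150 values of the 10 genes kept direction and call and 23 reversed, none of them past the threshold. In the other reading Lxn was 0.039 and Rpl5 -0.031. With position medians removed, Hspa1a was 0.041 and Top1 -0.27; without repeated values as well, Hspa1a was 0.045 (0.042 with medians over such probes) and Tcf3 0.013; with plate medians too, Actb was 0.034, Hspa1a 0.080, Rpn2 0.032 and Tcf3 0.048. Tcf3 was 0.13 without repeated values. With lean rat 4 counted once, Tcf3 was 0.12 without repeated values; with position medians removed as well, Actb was 0.013, Hspa1a 0.032, Rpn2 0.016 and Tcf3 0.014, and with those medians over such probes Actb was 0.0065, Hspa1a 0.025 and Rpn2 0.0016. Top1 was -0.0035 with quantile normalization, -0.011 with lean rat 4 counted once, and -0.053 to 0.12 without 1 array. Lxn lost its call in 15 alternatives besides the other reading. Its ratio stayed near -0.65 with a dye term (-0.65, adjusted p 0.0579), median centring (-0.65), 3 of the 4 sets of 3 arrays (-0.69 to -0.56), lean rat 4 counted once (-0.59) and position medians removed over all wells (-0.53). It was nearer 0, at -0.20 to -0.012, with medians over wells and in the settings without repeated values. It kept its call with equal spread (0.0441), quantile normalization (0.0439) and without obese rat 1 (0.0350). Rps9 and Top1 passed only without repeated values, a setting added for genes, and not with lean rat 4 counted once as well (0.0800 and 0.0660). The list tests were not run because no list had 5 members, and reading the values as natural logs was not needed because their spacing settled the base. The main test is itself paired, since each array already holds its pair. No further pairing was possible because all arrays form 1 group. Without intensities, signal over background limits every probe with a repeated value.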

Other observations

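The groups of plates compared here were chosen after seeing the data, and no test was run. Plates 74 and 75, with 768 probes, stood apart from the rest. Their median log2 ratio was -1.51 and -1.29 on the arrays with obese RNA in Cy5 (obese rats 5 and 4) and 0.81 and 0.74 on those with obese RNA in Cy3 (obese rats 3 and 1), and 97.0% of their probes held a repeated value on some array against 35.4% on plates 1 to 73.

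Source plates also differed along the plate numbers. From plates 1 to 20 to plates 21 to 72 the median log2 ratio moved by 0.16 and 0.07 on the arrays of obese rats 5 and 4, and by -0.08 and -0.18 on those of obese rats 3 and 1.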
